A study of Mus musculus with 3 samples.

How the data were processed

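Total RNA from the cortex of adult mice aged 16 weeks was compared between animals heterozygous for a Gtf2i allele named for a deletion of exon 2, written Gtf2i(+/Δex2), and wild-type animals. Per the labels' protocols, RNA was extracted with Trizol, every sample had an RNA integrity number of at least 7, and 500 ng was amplified by in vitro transcription and hybridised to Agilent arrays of 60-mer probes. Per the series' design text, each hybridised RNA was a pool from 3 to 5 mice of one genotype. Each of the 3 arrays carried mutant RNA in one colour and wild-type RNA in the other. Per the labels, the mutant RNA was in Cy3 on replicates 1 and 3 and in Cy5 on replicate 2. The labels do not say whether the 3 arrays used separate pools or the same pools, so p-values measure only the spread between these arrays, which may be technical. The number of arrays limits the precision. The labels give both genotypes the same mixed background, 98.4% C57BL/6J and 1.6% 129Sv/CD1.

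The authors deposited one table per array with a linear intensity for each of 44290 spots in 2 channels, already background-subtracted and normalized, per the deposited readme, which names GenePix as the image software and does not give the normalization method. The readme calls the channel columns corrected for the dye swap and the deposited fold change test over control. It calls a spot reliable when its foreground exceeds 2 times its background. The authors also deposited a log2 ratio in which repeated spots of one probe were collapsed, per the file headers and the readme. The value table of the series holds a score per spot that the authors made from the same ratio, a signed fold with ratios under 1 written as minus their inverse; it was identical to the fold column of each array at every spot. Its medians were -1.01, -1 and 1 on replicates 1, 2 and 3, and 0 columns of that table were left unused. Per the readme, the authors selected genes with limma at a B statistic above 0.

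The direction of the ratios, mutant over wild type, is likely and rests on 3 points: the sample titles put the mutant before the wild type, the readme defines the fold as test over control, and the control spots turn over with the dyes. The Pro25G control spots had a median log2 ratio of 4.51 on replicate 1, -4.54 on replicate 2 and 4.58 on replicate 3, so the columns hold genotypes and not dyes. With the dyes in the labels, this puts the mutant RNA in the numerator if those control spots carry a Cy3-labelled oligonucleotide. The level of Gtf2i was not used to set the direction.

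Of the 44290 spots, 41534 held gene probes and the rest were controls or empty spots. Spots of one probe were averaged, which gave 41174 probes. Reliable gene spots made up 67.8% of replicate 1, 64.4% of replicate 2 and 69.7% of replicate 3. Probes flagged reliable on at least 2 arrays were tested, 27530 in all. Probe accessions were matched without versions to a table of RefSeq genes on assembly GRCm38.p6, used only for names, gene lengths and gene order. It named 21445 probes, or 52.1%; among the tested probes 16550 were named, for 12721 genes, and 10980 were unnamed here.

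The planned loess normalization was meant for values not yet normalized. Because the deposited intensities already were, log2 ratios of the deposited channels were tested as they stood, and loess became an alternative chosen after the data were seen. Each probe's mean ratio was tested against 0 with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with the data.table package, version 1.17.8, and p-values were adjusted by the Benjamini-Hochberg method over all tested probes at a threshold of 0.05. Errors given as SD are the spread of the 3 arrays. Gene lists were tested with camera at a preset correlation of 0.01 between genes, adjusted over 27 lists. Figures were drawn with matplotlib 3.10.9 and pandas 2.3.3 in Python 3.11.15.

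The samples' groups, the tests, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule named Gtf2i and, among genes past the threshold with one sign on all 3 arrays, the 12 highest and 12 lowest mean log2 ratios, passing over RIKEN and predicted names. A gene was named by its probe with the smallest p, and disagreeing probes were stated. Within each list, up to 4 members with the smallest p were named; genes outside the rule are said to be so. A few genes that the rule takes are not reported here, though counts and list tests include them. A gene of a list counts as risen or fallen by its probe with the smallest p. The ribosomal protein and respiratory chain lists hold every gene whose symbol starts with set prefixes. These were Rpl or Rps for the first, and prefixes such as Ndufa, Sdh or Uqcr for the second. Both can therefore include genes that are not subunits, such as the kinase gene Rps6kb1 in the first. The lists were Williams-Beuren interval genes, genes reported as targets or partners of TFII-I, immediate early genes, ER stress genes, PI3K and AKT pathway genes, TGF-beta pathway genes, synaptic genes, ion channel genes, social neuropeptide and stress hormone genes, markers of GABAergic interneurons, glutamatergic neurons, astrocytes, oligodendrocytes, microglia, endothelial cells and pericytes, choroid plexus with ependyma and meninges, striatum, hippocampus, thalamus, hypothalamus with olfactory bulb, and blood cells, sex-linked genes, interferon-response genes, heat shock genes, circadian clock genes, ribosomal protein genes and mitochondrial respiratory chain genes.

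The calculation was tested on simulated ratios of 27530 probes on 3 arrays, 200 of them changed. It recovered 0% of changes of 0.25 on the log2 scale, 79% of changes of 0.5 with 9 false calls, and 98.5% of changes of 1 with 4 false calls; with no change it made 0 calls. Of 50 simulated lists shifted by 0.15, all 50 were called, as was 1 of 50 unshifted lists. In the data 9333 probes passed, far more than the 200 simulated changes, so these recovery rates do not carry over. The simulated probes also varied independently, so lists whose genes move together were not covered. Alternatives covered subtraction of each channel's median negative control with a floor of 1, median centring, scaling between arrays, the authors' signed folds, no filter and a stricter filter on dim probes, a dye term for each gene, eBayes with trend and robust options, array weights, leaving out each array, other thresholds, and averaging the probes of a gene. Negative controls had medians of 72.3 to 81.4 per channel, against medians of 204.1 to 206.1 for gene spots. Foreground and background columns were not used here, so the background correction itself was not varied. No genome build is named in the array tables, so no coordinates are given.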

Results

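Gtf2i encodes TFII-I, a general transcription factor whose gene lies in the chromosomal interval deleted in Williams-Beuren syndrome. The arrays addressed how transcript levels in adult mouse cortex differ when one copy of Gtf2i carries a deletion of exon 2. On each of 3 two-colour arrays a pool of RNA from Gtf2i(+/Δex2) cortex was set against a pool from wild-type cortex, with the dyes exchanged on replicate 2. Values are log2 ratios of mutant over wild type, a direction that is likely from the readme, the sample titles and the control spots. Across the 27530 tested probes, ratios correlated with Pearson r = 0.822 between replicates 1 and 2, which had opposite dyes, 0.783 between replicates 1 and 3, which had the same dyes, and 0.625 between replicates 2 and 3. These correlations are across probes, which are not independent replicates.

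**Figure D1:**
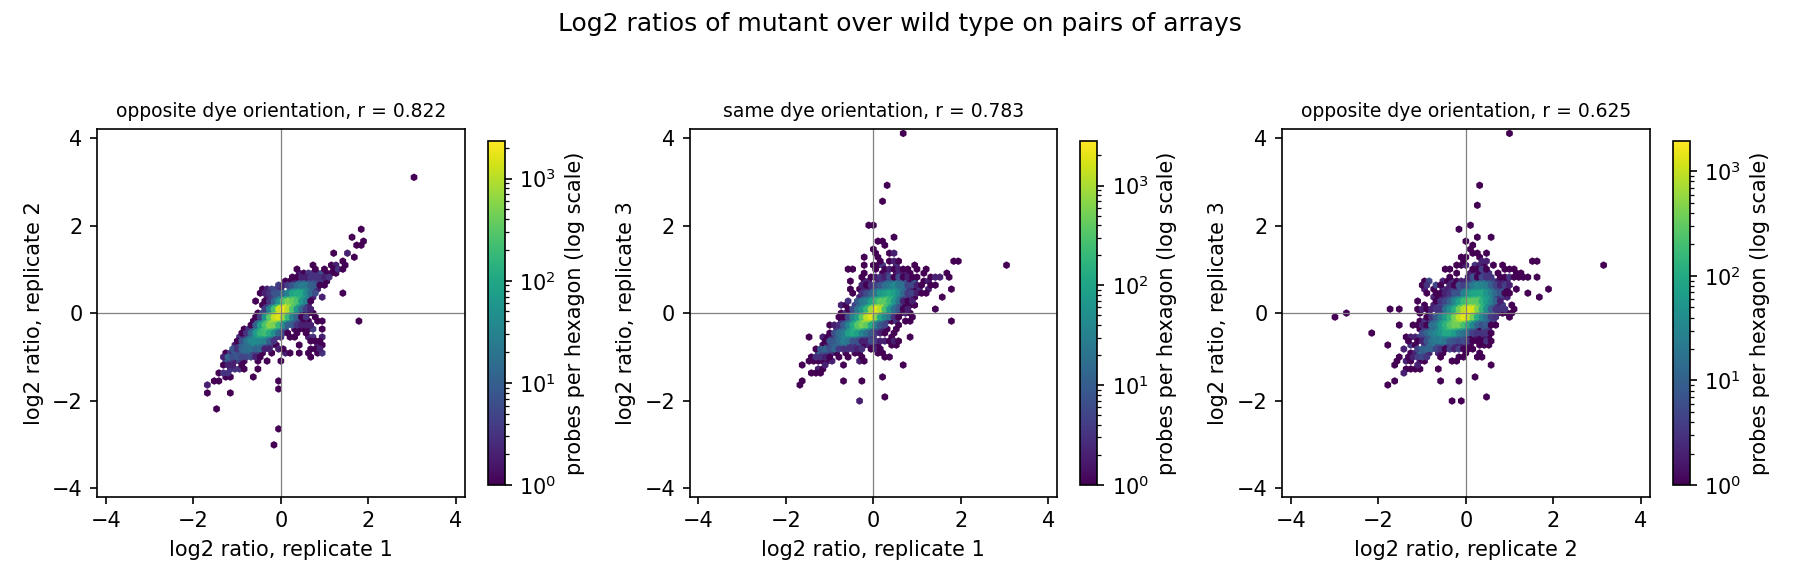
Log2 ratios (mutant over wild type) of the 27530 tested probes for each pair of arrays; both axes are log2 ratios and colour gives the number of probes per hexagon on a log scale. Probes lie along the diagonal in each panel, with Pearson r of 0.822, 0.783 and 0.625 from left to right.

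With the likely direction of the ratios, Gtf2i was lower in the mutant cortex on every array. Its probe A_52_P442585 had a log2 ratio of -0.47 ± 0.04 (SD, n = 3 arrays; limma adjusted p = 0.0026), a signal at 72% of wild type, with -0.46, -0.44 and -0.52 on the 3 arrays. Its brighter probe A_51_P499905 read -0.32 ± 0.05 (SD, n = 3, limma adjusted p = 0.00505), or 80.4% of wild type. With the level of the negative controls subtracted, A_52_P442585 read -0.61 and A_51_P499905 -0.33. Where these probes lie relative to exon 2 is not given in the sources used here, and a probe outside the deleted part does not check the genotype. Without replicate 1 the smaller fall no longer passed (limma adjusted p = 0.0559, the highest of 15 alternatives, which began at 8.67e-05).

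Changes in the mutant cortex were numerous and mostly small. The genes with the largest rises included Tmem107, a protein of the ciliary transition zone, at 1.41 ± 0.76, B3gnt2, a glycosyltransferase that builds polylactosamine chains, at 1.22 ± 0.76, and Cpeb2, which binds cytoplasmic polyadenylation elements, at 1.14 ± 0.34 (log2 ratio, SD, n = 3). The secreted factor gene Vash2 rose by 1.09 ± 0.13, the T-box factor gene Tbx20 by 1.02 ± 0.42, the phosphoinositide phosphatase gene Inpp5f by 0.99 ± 0.04 and the ligand gene Wnt3 by 0.97 ± 0.35. Tcf7l2, a transcription factor of the Wnt pathway, read 0.94 ± 0.71, Sh3bgrl 0.94 ± 0.07, Iah1 0.90 ± 0.19, the actin-related protein gene Actr2 0.87 ± 0.04 and the splicing factor gene Srsf1 0.86 ± 0.10. Their limma adjusted p ranged from 0.00178 for Inpp5f to 0.0403 for Tcf7l2. Tmem107 and B3gnt2 lost their call without replicate 1 (limma adjusted p = 0.0666 and 0.0948), without replicate 2 (0.0692 and 0.0956) and with replicates 1 and 2 averaged as 1 (0.0694 and 0.0963). Tcf7l2 lost its call in 5 of 15 alternatives (up to 0.0877) and read 0.53 without replicate 3. Many of these rises came from dim probes. Those of Cpeb2, Vash2, Tbx20, Inpp5f, Wnt3, Iah1 and Srsf1 failed the stricter filter on dim probes. Their mean signals ran from 195.3 for Tbx20 to 301.3 for Srsf1, where medians of gene spots were 204.1 to 206.1. Sizes of dim probes depended on the background: with the level of the negative controls subtracted Tbx20 read 1.71, Cpeb2 1.63 and Vash2 1.61, all above Tmem107 at 1.47.

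The genes with the largest falls included Fam110a (-1.49 ± 0.28), the synaptotagmin gene Syt10 (-1.39 ± 0.25) and Lars2, the mitochondrial leucyl-tRNA synthetase (-1.39 ± 0.83; log2 ratio, SD, n = 3). Ifitm3, an interferon-induced membrane protein, fell by 1.32 on the log2 scale, the Fos family gene Fosl2 by 1.24, and Pigt, a subunit of the enzyme that attaches GPI anchors, by 1.24. Cdk5r2, an activator of the neuronal kinase Cdk5, fell by 1.21, the homeobox gene Tlx2 by 1.14, the ubiquitin ligase gene Lnx1 by 1.13, the zinc finger gene Zfp628 by 1.11 and Ms4a19 by 1.10. The probes of these genes were bright, with mean signals from 1888 for Cdk5r2 to 30650 for Pigt and 5679 for Tlx2. Medians of gene spots were 204.1 to 206.1. Whether each signal comes from the named transcript was not tested. The adjusted p of these genes ran from 0.0016 for Fosl2 to 0.0206 for Lars2 in the limma fit; Lars2 lost its call without replicate 1 (0.0798), without replicate 2 (0.0571) and with both averaged as 1 (0.0722).

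Other probes of these genes, where any were tested, often read differently. Among the falls, Fam110a, Lars2, Ifitm3, Cdk5r2, Tlx2, Zfp628 and Ms4a19 had no other tested probe. Among the rises, Tmem107, Cpeb2, Vash2, Tbx20, Wnt3, Iah1 and Actr2 had none. Each of these changes rests on 1 probe. Fosl2 had a probe at -1.24 and another at 0.34, both past the threshold. The other probes of Syt10 (-0.08), Pigt (0.01), Lnx1 (0.02 and -0.02) and Tcf7l2 (-0.01) did not pass. The other probes of B3gnt2 (0.25), Inpp5f (0.24), Sh3bgrl (0.46) and Srsf1 (0.28) rose, by less. Tcf7l2 stood at 1.76 on replicate 3 against 0.46 and 0.60 on the other arrays. Tmem107 stood at 0.53 on replicate 3 against 1.80 and 1.89, B3gnt2 at 0.35 against 1.58 and 1.72, and Lars2 at -0.51 against -1.49 and -2.16.

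**Figure D2:**
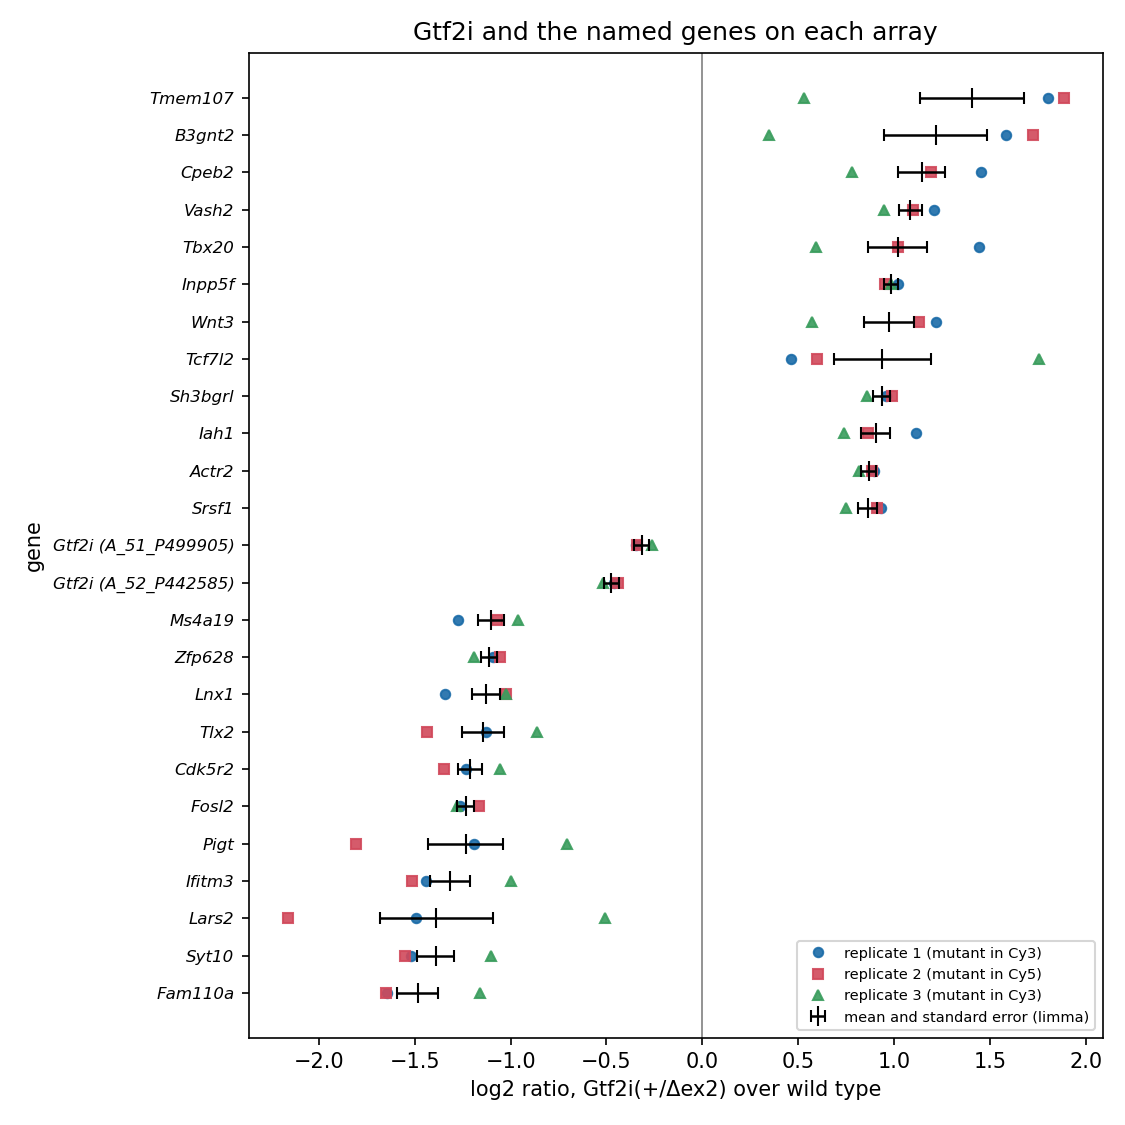
Log2 ratio of mutant over wild type (horizontal axis) for both Gtf2i probes and 23 named genes; coloured points are the 3 arrays, and the black bar is the mean with its limma standard error. Each gene has one sign on all arrays, which the naming rule required of all but Gtf2i. Replicate 3 stands apart from the others for Tmem107, B3gnt2 and Tcf7l2, and all 3 arrays differ for Lars2.

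In all, 9333 of 27530 probes, 33.9%, passed the threshold in the limma fit, 4141 higher and 5192 lower in the mutant, with a median absolute log2 ratio of 0.264. All 9333 had one sign on the 3 arrays, which a call largely requires, as did 65.1% of tested probes. At a change of at least 1.5-fold the count was 552, with 143 higher and 409 lower, and at 2-fold it was 73, with 17 higher and 56 lower. The authors' rule of B above 0 gave 2661 probes. The count fell to 2409 without replicate 1, was 5120 with replicates 1 and 2 averaged and counted as 1, and reached 18617 with array weights. Without replicate 3 it was 9885.

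Most of the 27 lists leaned lower in the mutant by camera, so a downward lean was not particular to the 4 that it called. Genes of the synapse were lower in the mutant as a group. Of 30 measured synaptic genes 20 fell and 3 rose, and 22 fell and 4 rose when adjusted over the list alone. Syt1, the calcium sensor of vesicle release, fell by 0.63 on the log2 scale at its best probe, Syn1, which encodes synapsin, by 0.56, the scaffold gene Homer2 by 0.40 and the AMPA receptor gene Gria1 by 0.52. Other probes of Syt1 ranged from -0.87 to 0.09, and those of Gria1 reached 0.10. The camera test placed the list below other genes (adjusted p = 0.000508). The call was lost in the camera run that estimates the correlation between genes, 0.036 for this list (adjusted p = 0.651). That run takes its degrees of freedom from the 3 arrays, so it had little power for any list. It cannot settle whether correlation between genes matters here.

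Ribosomal protein genes and genes of the mitochondrial respiratory chain were lower as well. Of 92 genes whose symbols start with Rpl or Rps, 46 fell and 5 rose, with the same counts adjusted over the list alone. The list was led by Rps26 (-0.63 ± 0.04), Rpl10 (-0.68 ± 0.07), Rpl7 (-0.54 ± 0.04) and Rpl34 (-0.71 ± 0.12, SD, n = 3). The list shifted by a mean of -0.12 (camera adjusted p = 6.53e-05, or adjusted p = 0.514 with an estimated correlation). Its estimated correlation of -0.003 lay below the preset 0.01, so a higher correlation between its genes does not account for the lost call. Its unadjusted camera p went from 2.42e-06 to 0.019 in that run, which rests on the few degrees of freedom of 3 arrays. Of 85 genes taken by symbol prefix for the respiratory chain, 40 fell and 8 rose, or 45 and 11 adjusted over the list alone. Among them Atp5b and Atp5h, both of the ATP synthase, read -0.56 and -0.44, the cytochrome oxidase gene Cox4i1 read -0.40 and Atp5j2 read -0.51, while another probe of Atp5b read 0.29. This list shifted by a mean of -0.10 (camera adjusted p = 0.00363; adjusted p = 0.651 with an estimated correlation). Across all 12721 named genes, 23.6% fell and 17.1% rose, shares not matched for brightness or for probes per gene. Calls were more frequent among bright probes. Of the 6883 dimmest tested probes 8.9% were called lower and 5.3% higher, against 26.6% and 23.6% of the 6883 brightest. Whether the list counts exceed those of equally bright genes was not tested.

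Astrocyte markers were the remaining group that camera called lower. Of 13 measured genes 7 fell and 2 rose, with the same counts adjusted over the list alone. The 2 rises were Sox9 (0.57) and Gja1 (0.39), both outside the naming rule, while another probe of Sox9 read -0.29. The water channel gene Aqp4 fell by 0.78 on the log2 scale, the glutamate transporter gene Slc1a2 by 0.64, the aldolase gene Aldoc by 0.56 and the folate enzyme gene Aldh1l1 by 0.45, while other probes of Aqp4 and Slc1a2 reached -0.07 and -0.01. The camera adjusted p was 0.0444, or adjusted p = 0.693 with an estimated correlation, and the call was lost under 7 of 12 alternatives, among them leaving out replicate 1 (0.0687) or replicate 2 (0.0559), with adjusted p from 0.022 to 0.693. With an estimated correlation 0 of the 27 lists were called, and 1 had an unadjusted p under 0.05. The rotation test fry, which asks whether a list's genes move one way and does not compare them with other genes, called 10 lists: the 4 that camera called, TGF-beta pathway genes (adjusted p = 0.00645), glutamatergic markers (0.0082), microglia markers (0.0247), clock genes (0.0265) and Williams-Beuren interval genes (0.0319) as lower, and choroid plexus, ependymal and meningeal markers (0.0451) as higher.

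**Figure D3:**
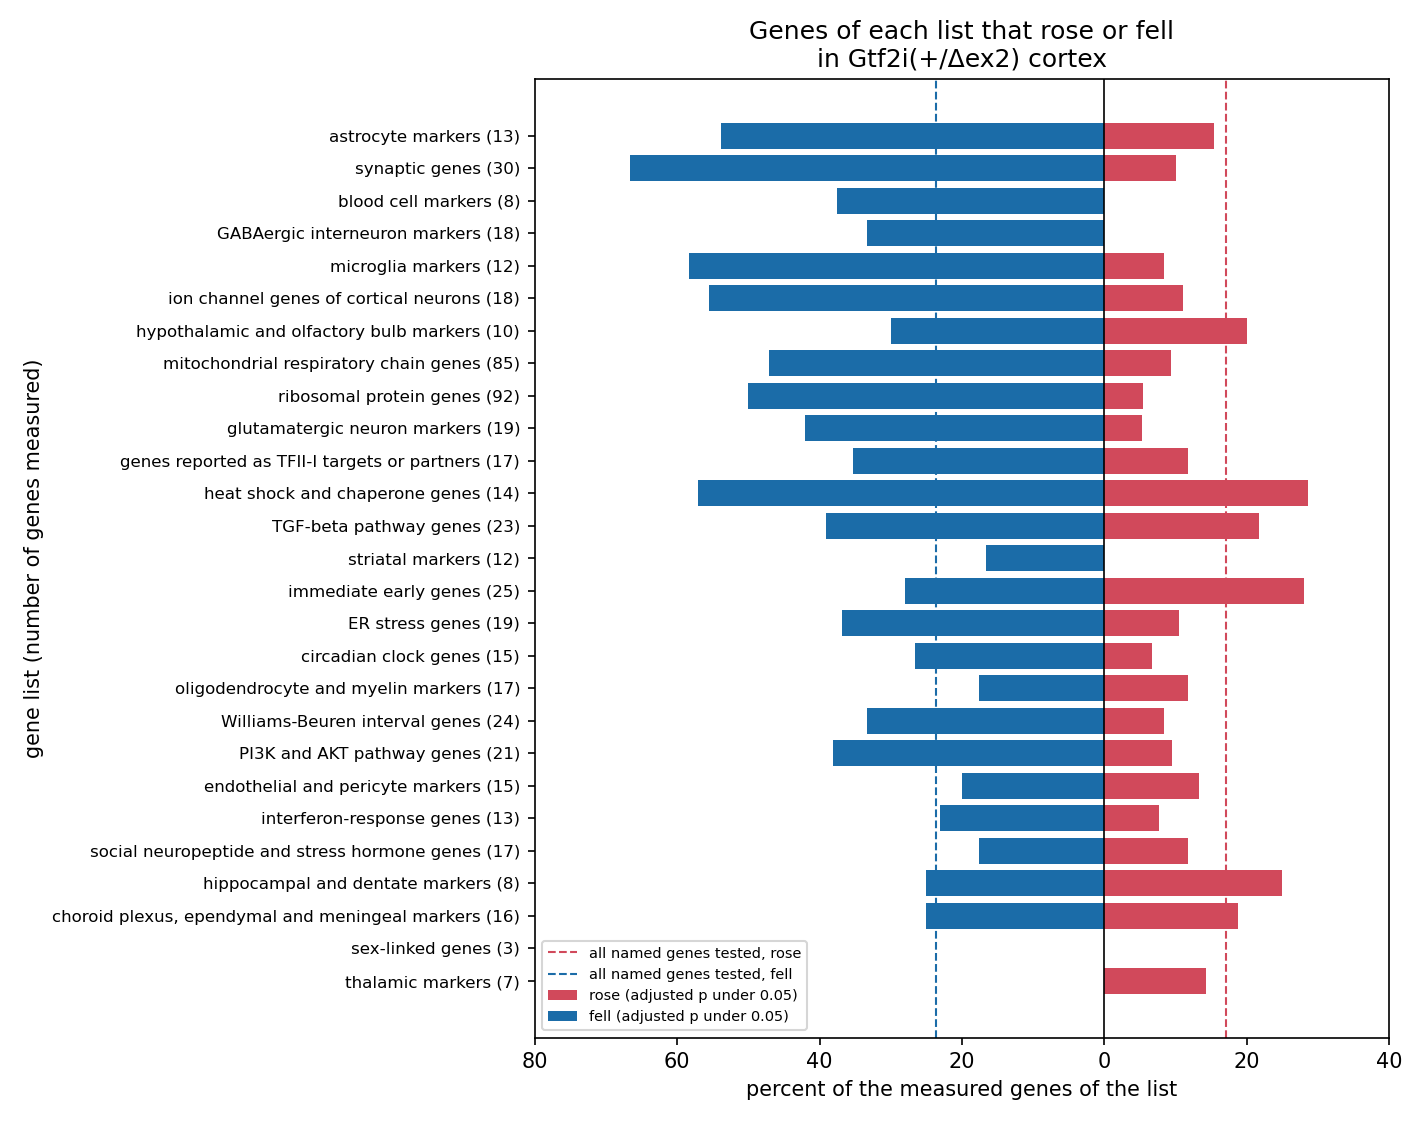
Percent of the measured genes of each list that fell (blue, left) or rose (red, right) at a limma adjusted p under 0.05, with the number of genes measured in parentheses and lists ordered by the median log2 ratio of their probes. Dashed lines mark the shares among all named genes, 23.6% fallen and 17.1% risen, not matched for brightness. Most lists lie beyond the line for falls, synaptic, ribosomal, respiratory chain and astrocyte genes among them.

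Markers of the neuron classes, ion channels and microglia markers leaned the same way without passing the list test. Of 18 GABAergic interneuron markers 6 fell and 0 rose, among them Htr3a (-1.07), Sst (-0.57) and Npy (-0.24), with a camera adjusted p of 0.153 and mean log2 ratios of -0.211, -0.189 and -0.025 on replicates 1 to 3. Of 19 glutamatergic markers 8 fell and 1 rose, or 9 and 2 adjusted over the list alone, with Cux2 at -0.45, Camk2a at -0.44, Etv1 at -0.32 and the vesicular glutamate transporter gene Slc17a7 at -0.41 (camera adjusted p = 0.0677). Of 18 ion channel genes 10 fell and 2 rose, or 10 and 3 adjusted over the list alone, with Kcnd2 at -0.68, Cacnb4 at -0.57 and Kcnq3 at -0.48 (camera adjusted p = 0.0797; means of -0.165, -0.142 and -0.043 on replicates 1 to 3). The other probe of Kcnd2 read 0.20. Of 12 microglia markers 7 fell and 1 rose, among them Tyrobp (-0.26), Tmem119 (-0.24), the fractalkine receptor gene Cx3cr1 (-0.30) and Laptm5 (-0.28), with a camera adjusted p of 0.0677 and means of -0.120, -0.103 and -0.134 on replicates 1 to 3.

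Oligodendrocyte and vessel markers went both ways. Of 17 oligodendrocyte markers 3 fell and 2 rose: Olig1 (-0.54), Cnp (-0.70) and Mobp (-0.25) fell, and Mal (0.26) was among the rises (camera adjusted p = 0.476). Of 15 endothelial and pericyte markers 3 fell and 2 rose; the pericyte genes Rgs5 (0.54) and Pdgfrb (0.36) rose, Vtn (-0.31) fell, and the probes of Acta2 read -0.32 and 0.15 (camera adjusted p = 0.682). For these lists, the microglia markers and the interneuron markers the counts adjusted over the list alone were the same.

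Genes of the Williams-Beuren interval, Gtf2i among them, passed the threshold about as often as all named genes, of which 40.7% passed. That share was not matched for brightness. Of 24 measured interval genes 8 fell and 2 rose, also when adjusted over the list alone, and the list as a whole was not called (camera adjusted p = 0.325). Besides Gtf2i, the falls included the chromatin remodelling gene Baz1b (-0.44 ± 0.11), the syntaxin gene Stx1a (-0.38 ± 0.16) and Bud23 (-0.23 ± 0.08; SD, n = 3). Gtf2ird1, the related gene beside Gtf2i and outside the naming rule, had probes from -0.06 to 0.48. Rfc2, also outside the rule and counted as fallen, had probes at -0.18 and 0.23.

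Genes reported as targets or partners of TFII-I went both ways. Of 17 measured, 6 fell and 2 rose, or 7 and 2 adjusted over the list alone (camera adjusted p = 0.107). The histone deacetylase gene Hdac2 rose by 0.44 ± 0.07, while the ER chaperone genes Hsp90b1 and Calr read -0.47 ± 0.11 and -0.35 ± 0.09 (SD, n = 3). The other probe of Hsp90b1 read -0.04.

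Signalling genes and immediate early genes were mixed. Of 21 PI3K and AKT pathway genes 8 fell and 2 rose, with Gsk3b at -0.73 and Mtor at -0.46 against Tsc2 at 0.29 (camera adjusted p = 0.476). Of 23 TGF-beta pathway genes 9 fell and 5 rose, with Id2 at -0.66, Ski at -0.52, Smad4 at -0.37 and Smad3 at -0.31, and another probe of Smad4 at 0.10 (camera adjusted p = 0.349). Both lists had the same counts adjusted over the list alone. Of 25 immediate early genes 7 fell and 7 rose, or 8 and 8 adjusted over the list alone (camera adjusted p = 0.531). Besides Fosl2, the growth factor gene Bdnf had probes at 0.30 and -0.14 and Gadd45b at 0.38 and -0.26, and Egr2 rose by 0.32. Of 17 social neuropeptide and stress hormone genes 3 fell and 2 rose, or 3 and 1 adjusted over the list alone, with the serotonin receptor gene Htr2a at -0.84, Maoa at 0.24, Crhbp at -0.22 and Drd4 at -0.23; camera leaned up (adjusted p = 0.409) and fry down (adjusted p = 0.378).

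Thalamic and striatal markers read differently on the 3 arrays, whereas the array means of hippocampal markers (0.065, 0.035 and 0.01) and of choroid plexus, ependymal and meningeal markers (0.03, 0.014 and -0.003) lay within 0.054 and 0.033 of each other. The 14 probes of thalamic markers had a mean log2 ratio of 0.70 on replicate 3, against -0.04 and -0.05 on replicates 1 and 2, and Tcf7l2 was the 1 gene of 7 that passed; adjusted over the list alone 0 passed, as against 2 at an unadjusted p under 0.05, Tcf7l2 higher and Calb2 lower. Zic1 read 0.52 ± 0.73, Rora 0.22 ± 0.29 and Calb2 -0.27 ± 0.29 (SD, n = 3), none past the threshold. The 15 probes of striatal markers averaged -0.15, -0.27 and 0.16 on replicates 1 to 3; of 12 genes 2 fell, Pde10a (-0.64) and Adora2a (-0.26), and 1 adjusted over the list alone, while Drd2 (-0.36) and Rxrg (0.42) did not pass. Neither list was called (camera adjusted p = 0.349 for each).

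Of 16 choroid plexus, ependymal and meningeal markers 4 fell and 3 rose, also when adjusted over the list alone: Clic6 (0.53) and Slc13a4 (0.27) were among the rises and Aldh1a1 (-0.61) and Ptgds (-0.55) among the falls (camera adjusted p = 0.349). Of 8 blood cell markers 3 fell and 0 rose, also when adjusted over the list alone, with the globin genes Hba-a1 at -0.65 and Hbb-bt at -0.46 and the heme enzyme gene Alas2 at -0.25; Ptprc read 0.12 and did not pass (camera adjusted p = 0.151). The 11 probes of blood markers averaged -0.30, -0.31 and -0.03 on replicates 1, 2 and 3. Of the 3 Y-linked genes measured, Eif2s3y (0.18), Kdm5d (0.08) and Ddx3y (0.02), 0 passed in the limma fit, also when adjusted over the list alone, and 1 had an unadjusted p under 0.05 (camera adjusted p = 0.375 for the sex-linked list).

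No probe passed the test for the dye. In the limma contrast of Cy5 over Cy3 on the same 3 arrays, 0 of 27530 probes passed and 213 had an unadjusted p under 0.05, where chance would give 1376; differences between genotypes enter the spread of this contrast and lower its power. With a dye term for each gene beside the genotype, 0 probes passed for the dye in the limma fit. There 2409 had an unadjusted p under 0.05, more than the 1376 of chance, so a dye effect on some probes is not excluded. In the fit with the dye term 9530 probes passed for the genotype, of which 8455 were among the 9333.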

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

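Loess, the deposited collapsed ratios, B above 0, the averaging of replicates 1 and 2, the averaging of probes of one gene in the list tests and every alternative of the dye contrast were chosen after the data were seen. The main fit called 9333 of 27530 tested probes. The count was 18617 with array weights, 5120 with replicates 1 and 2 averaged as 1, 552 at 1.5-fold or more and 2661 at B above 0. With 1 array left out it was 2409 to 9885, the lowest without replicate 1. Fewer arrays and stricter thresholds enter the lower counts by construction, and other causes were not tested. The count stayed between 7191 and 12299 under the other settings. Gtf2i kept its direction throughout; its smaller fall ranged from -0.34 to -0.30 with 1 array left out and lost its call without replicate 1. Of 27 lists, 4 were called in the main test and 3 to 8 with 1 array left out, the most without replicate 3. With an estimated correlation 0 were called, and by fry 10. A higher correlation does not account for the lost call of the ribosomal list, whose estimate of -0.003 lay below the preset 0.01. Microglia and glutamatergic markers, with estimates of -0.04 and -0.036, also went from an unadjusted camera p of 0.0151 and 0.0144 to 0.121 and 0.113. The run with an estimated correlation rests on the few degrees of freedom of 3 arrays, which leaves it little power. Other causes of these differences were not tested beyond the tests' own construction. The dye contrast called 0 probes in limma under each setting run, with 210 to 2409 at an unadjusted p under 0.05. The 24 genes that the naming rule took by size kept their direction in 353 of 353 comparisons and their call in 339. Because the rule asked for one sign on all arrays, leaving out, averaging or weighting arrays could not turn a direction. The 14 lost calls were those of Tmem107, B3gnt2 and Lars2 without replicate 1, without replicate 2 and with both averaged, and of Tcf7l2 in 5 settings. With the negative-control level subtracted Tbx20 read 1.71 instead of 1.02, and Tcf7l2 read 0.56 with array weights and 0.53 without replicate 3 instead of 0.94. Named probes that fail the strict filter have no value there. Signal over background limits dim genes: 27530 of 41174 probes were reliable on 2 arrays, and 16469 were present in both channels of all 3.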

Other observations

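Stress and clock genes changed in both directions. Of 14 measured heat shock and chaperone genes 8 fell and 4 rose, also when adjusted over the list alone, with Hspa8 (-0.48), Hspa4 (-0.36) and Hspb1 (-0.35) lower and Hspa4l (0.34) higher (camera adjusted p = 0.314); the other probe of Hspa4 read 0.06. Of 19 ER stress genes 7 fell and 2 rose, also when adjusted over the list alone: Hyou1 rose by 0.40, and Hsp90b1 (-0.47), Dnajc3 (-0.65) and Calr (-0.35) fell, with other probes of Dnajc3 up to 0.15 (camera adjusted p = 0.153). Of 15 clock genes 4 fell and 1 rose, also when adjusted over the list alone, with the PAR bZIP genes Tef (-0.52) and Hlf (-0.36) and the cryptochrome genes Cry2 (-0.37) and Cry1 (0.14; camera adjusted p = 0.234).

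Of 13 interferon-response genes 3 fell and 1 rose, also when adjusted over the list alone, with B2m at -0.54, H2-D1 at -0.22 and Irf9 at -0.20 (camera adjusted p = 0.657). Of 10 hypothalamic and olfactory bulb markers 3 fell and 2 rose, also when adjusted over the list alone, with Trh at -0.42, Cdhr1 at -0.38, Pomc at -0.94 ± 0.56 and Tbx21 at 0.16 (SD, n = 3; camera adjusted p = 0.349). Of 8 hippocampal markers 2 fell and 2 rose, or 3 and 2 adjusted over the list alone, with Mpped1 at 0.50, Wfs1 at 0.34, Fibcd1 at -0.36 and C1ql2 at -0.23 (camera adjusted p = 0.657).

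The tests of sign assignments, of pairs of probes across genes, of which array stands apart and of dye as an explanation were chosen after the results were seen (the dye contrast and the fit with a dye term were planned), as were the limits of -0.8 and 0.6 that define the largest changes and the intensity limit of 9.5.

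The largest changes were weighed first. The 72 named probes that fell below -0.8 had a median log2 ratio of -0.943, and the 45 other tested probes of the same genes had a median of -0.024, with 13 fallen and 5 risen. Loess left the 72 probes at a median of -0.946, which argues against an intensity trend. Signal of single probes, such as cross-hybridisation or a transcript end that 1 probe alone reads, is therefore a candidate explanation for some of these falls, although the other probes were dimmer (median log2 intensity 8.8 against 11.02), isoforms stay open, and probes picked as extreme are followed by milder ones in any case. With the limit at -0.6 and -1 the median of the other probes was -0.103 and 0.008. At -0.6, however, 60 of the 140 other probes had fallen, and the others with a mean log2 intensity over 9.5 had a median of -0.194 (53 probes), as against -0.159 (14 probes) at -0.8 and 0.115 (3 probes) at -1, so part of the falls may be shared by the gene. In contrast, for the 64 probes that rose above 0.6, the 30 other probes had a median of 0.19, with 14 risen, and the value ran from 0.055 to 0.283 with the limit at 0.5 and 0.8. Those over the same intensity had medians of 0.339 (13 probes) at 0.6, 0.206 (29 probes) at 0.5 and 0.329 (5 probes) at 0.8, which leans towards rises shared by the gene, but over all the other probes this is not settled.

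The number of called probes was weighed second. A dye term for each gene left 9530 calls, and gene length followed the ratios with a Spearman rho of -0.03 over 12721 genes, so neither dye bias nor a trend with length accounts for 9333 calls. Among 3270 genes with at least 2 tested probes, the ratios of 2 probes of one gene correlated with r = 0.296, above the highest of 1000 shuffles (0.064) and below the 0.783 that is the median between arrays for one probe; of 635 such pairs with both probes called, 477 shared a direction. The calls may thus mix changes of genes with changes of single probes, and the shares are not known. The 4 assignments of signs to 3 arrays are too few for a share under 0.05: 1 of them, the real one, gave 9333 calls, and the highest other gave 0; differences between the pools apart from genotype and the genotype itself stay open.

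Replicate 3 was weighed last, because thalamic, striatal and blood cell markers set it apart. Among the 1000 tested probes with the largest SD it was the array farthest from the others in 63%, replicate 2 in 33.9% and replicate 1 in 3.1%, where chance gives 33.3% each. Over all tested probes the order was another, with 42.5% for replicate 2, 37% for replicate 3 and 20.5% for replicate 1. A dye effect would single out replicate 2, and shared pools on replicates 1 and 2 would single out replicate 3; since the sets of probes disagree, both stay open for the arrays as a whole. The thalamic markers did not follow the dyes: replicates 1 and 3, of the same dyes, averaged -0.037 and 0.699, and replicates 1 and 2, of opposite dyes, -0.037 and -0.052. For them a difference in dissection, or in the pools, stays open. Counting replicates 1 and 2 as 1 left 5120 probes, 5101 of them among the 9333.

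Of the 100 tested genes nearest to Gtf2i in gene order, 15% passed the threshold with an absolute log2 ratio over 0.3, against a median of 17% in 109 windows of the same size on other chromosomes. An excess that DNA of the other strain carried along with the altered allele might bring was not seen at this size of window.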
